A study of Escherichia coli str. K-12 substr. MG1655 with 6 samples.

How the data were processed

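RNA was measured by sequencing in 6 libraries of Escherichia coli K-12 MG1655, 3 from the wild type (WT) and 3 from a mutant lacking recN, which were untreated or had been given mitomycin C (MMC) for 20 or 40 min. Each of the 6 groups held 1 library. Per the labels' protocols, RNA was purified with a GeneJET kit, and libraries were made with an Illumina TruSeq kit and sequenced on a Genome Analyzer. Per the submitters' processing notes, CASAVA 1.8.2 and FastQC 0.10.1 were used. The aligner, the counting program and the genome build are not given in the sources used here, nor is it stated whether counting used strand.

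Per the file headers, each deposited table held raw counts per gene, and these were the values analysed. Fractions had been dropped from the raw counts, since the normalized counts divided by their constant left a remainder. The normalized counts that the authors deposited, a signal equal to the raw count times 1 constant per library, were used only for that check. The deposited RPKM and expression columns hold whole numbers, which makes each of them a score rounded by the authors, and they were not tested. Of 4318 locus tags, 4314 were found in the RefSeq table used for names, and 4114 of 4139 coding genes had the same start and end there. Coordinates are those of the deposited tables. Rows of predicted RNAs, which have no locus tag, were kept out of library sizes and tests. They held between 1.38% of the counts in untreated recN and 3.53% in WT at 20 min.

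Genes with at least 10 counts in at least 2 libraries were tested, which kept 4298 and left out 20. Counts were analysed with edgeR 4.0.16 (TMM normalization, quasi-likelihood test, Benjamini-Hochberg adjustment with a threshold of 0.05) in R 4.3.3. The model held strain and treatment as additive terms over all 6 libraries and had 2 residual degrees of freedom. In it the strains served as the repeat of each treatment, and the conditions as the repeat of each strain, so that its spread includes any response that differs between strains. Standard errors are the log2 fold change divided by the root of the F statistic. The test added 8.01 prior degrees of freedom, taken from the spread of all genes. Standard errors and p-values therefore rest more on the spread of other genes than on the gene's own. The labels do not say whether the libraries came from separate experiments, so p-values measure only the spread between these libraries. Comparisons of 2 libraries used log2 CPM (counts scaled to the normalized library size) with a prior count of 2. They have no replicate check and no p-value.

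The 26 gene lists, the tests and the rule for named genes were fixed before the data were examined. Of 720 list entries, 691 were matched. In the additive fit each list was given as its number of members past the threshold and by camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one. The estimated setting rests on the 2 residual degrees of freedom, so it rarely reaches a small p-value whatever the correlation. For 40 against 20 min the toxin-antitoxin list had an estimated correlation of -0.0364, below the preset one. Its camera p still went from 0.0284 to 0.137. A list that fails there is therefore not shown to be unchanged. In 2 libraries a list was given as its median log2 ratio, without recN itself, and that median's percentile among 10000 random lists matched on mean expression. Named genes were recN, the 10 highest and 10 lowest genes past the threshold at each time with the same sign in both strains, the members of the LexA list, up to 4 members of each other list with the greatest change at 40 min, and the 5 highest and 5 lowest of the strain comparison, of the difference of response and of each single response. Where fewer than 5 genes passed in the strain comparison, genes of the same sign in all 3 conditions were taken and are said not to have passed. Another 3 lists were written after the values were seen and are used only in the closing section.

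The alternatives tried were DESeq2 1.42.0, other scalings, other filters and prior counts, coding genes alone, the fit without its covariate, and each library left out in turn. The fit was tested on simulated counts for 4298 genes, of which 200 were changed at 40 min. With the fitted dispersion of 0.0226 it recovered 73% of the 2-fold and 99% of the 4-fold changes at 40 min, with 8 false calls among 180. The data gave 2089 calls at 40 min, far more than the genes changed in the simulation, so these rates may not hold for them. Intervals for counts cover counting error only. Genes with near-identical copies, such as tRNA genes, rRNA genes and insertion sequences, and genes that overlap another are uncertain, because reads can be shared between them.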

Results

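The series followed transcription in E. coli after DNA damage by mitomycin C (MMC), a drug that cross-links DNA, in WT and in a recN mutant. RecN is a protein of the SMC family that acts in the repair of double-strand breaks, and its gene belongs to the SOS response, which the repressor LexA controls. Cells were grown in minimal medium with casamino acids and glucose to an optical density of 0.2, and MMC was given at 10 µg/ml. There was 1 library for each strain at each of 3 conditions (untreated, 20 min, 40 min). The labels give no untreated library taken 20 or 40 min later. Changes after MMC can therefore not be told apart from those over the same time without MMC. In WT the counts in annotated genes summed to 6083401 untreated, 7080235 at 20 min and 4273965 at 40 min. In recN they summed to 10594013, 5908847 and 4263078.

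The targeted gene was read first. The recN gene (b2616, plus strand, 2751795 to 2753456) had 502 counts in untreated WT, 15774 in WT at 20 min and 5605 at 40 min, or 80.9, 1806 and 1717 CPM (counts scaled to the normalized library size). In the recN libraries it had 8, 7 and 4 counts, at most 1.18 CPM, and the exact 95% Poisson intervals of these counts were 3.45 to 15.8, 2.81 to 14.4 and 1.09 to 10.2. The strain labels and the WT treatment labels therefore match the gene's level.

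**Figure D1:**
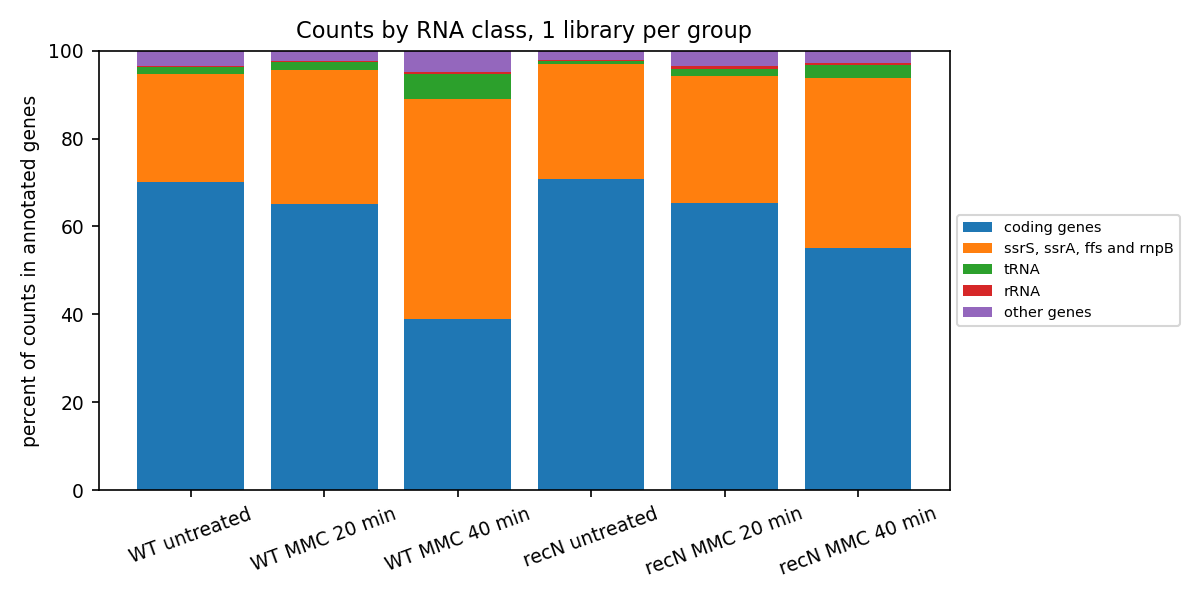
Percent of counts in annotated genes (vertical axis) by RNA class for the 6 libraries (horizontal axis), 1 library per bar. The ssrS, ssrA, ffs and rnpB RNAs together took 24.7% in untreated WT and 50.1% in WT at 40 min.

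The RNA classes differed in their share between libraries. Coding genes took 70.1% of the counts in untreated WT, 65.0% at 20 min and 38.9% at 40 min, and 70.9%, 65.3% and 55.2% in recN. The abundant small RNAs ssrS (6S RNA), ssrA (tmRNA), ffs (4.5S RNA) and rnpB (RNase P RNA) together took 24.7%, 30.5% and 50.1% in WT and 26.1%, 28.9% and 38.7% in recN. All changes below are relative to the scaling of each library.

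The first comparison asked which genes differ between 20 min of MMC and the untreated libraries on average over both strains. The fit does not require that both strains move: recN itself passed on WT alone. LexA-controlled genes rose most: 28 of 33 tested members of the LexA list passed the threshold upwards and 0 downwards. The list's median log2 fold change was 1.54, or 1.49 without recN itself. sulA (b0958, 1020410 to 1020919), the inhibitor of cell division, rose by a log2 fold change of 4.07 ± 0.34 (SE; 2 libraries per condition, edgeR adjusted p = 5.72e-05). It stood at 145 CPM in untreated WT and 3337 at 20 min, and at 423 and 5438 CPM in recN. dinI, yebG and recA, the recombinase that triggers LexA cleavage, rose by 3.85 ± 0.30, 3.70 ± 0.33 and 3.57 ± 0.33, and the translesion polymerase genes umuD, umuC and dinB by 3.39 ± 0.19, 2.95 ± 0.27 and 2.47 ± 0.19. The toxin gene tisB rose by 3.42 ± 0.39 and dinD by 2.82 ± 0.40. recN itself had a fitted value of 3.88 ± 0.71, which rests on WT.

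Other members of the list rose less. The nucleotide excision repair genes uvrA, uvrB and uvrD rose by 2.07 ± 0.21, 1.81 ± 0.21 and 0.63 ± 0.20, lexA by 1.95 ± 0.22, polB by 1.36 ± 0.17 and the branch migration genes ruvA and ruvB by 0.99 ± 0.17 and 0.90 ± 0.17. ssb, ftsK, symE, hokE and ybfE did not pass at 20 min, with log2 fold changes of 0.32, 0.48, 0.66, 0.23 and -0.38. Adjusted over the list alone, 30 members passed upwards.

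**Figure D2:**
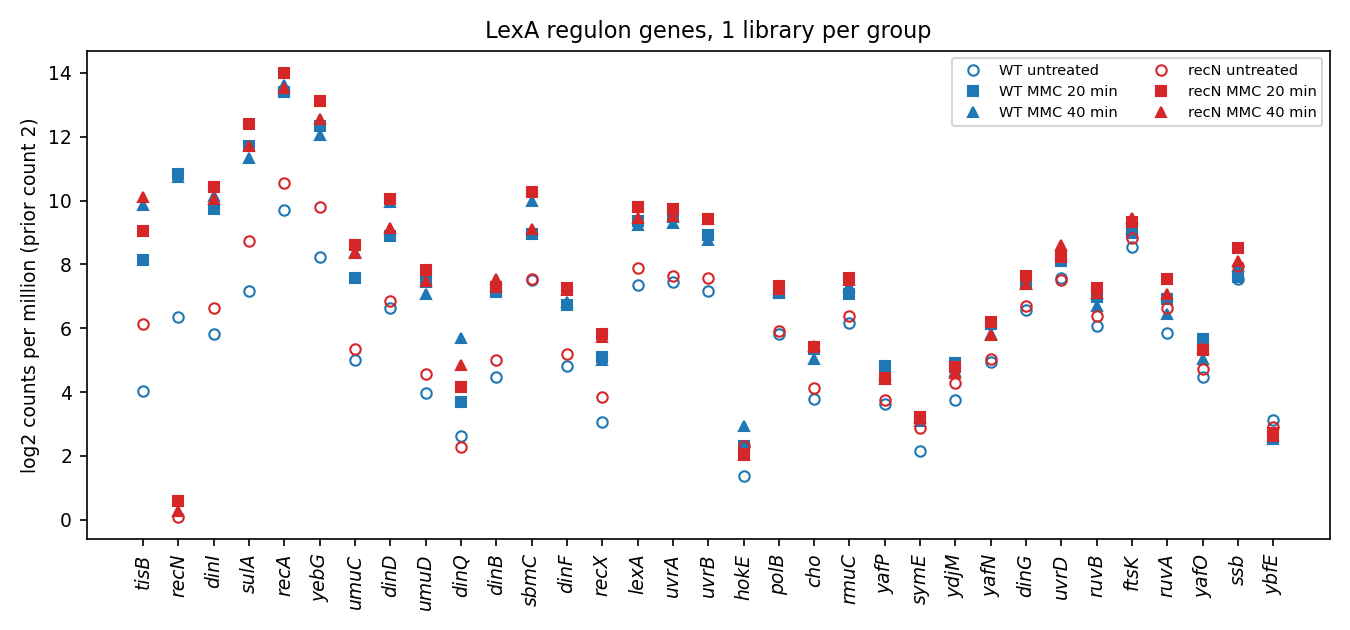
Level of each LexA list member (horizontal axis, ordered by the WT ratio at 40 min) as log2 CPM (vertical axis), with 1 point per library and open symbols for untreated libraries. sulA lies at 145 CPM in untreated WT and at 3337 CPM in WT at 20 min.

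The genes that fell most at 20 min serve nitrite and nitrate reduction and copper export. nirD, nirB and nirC, for nitrite reductase and nitrite transport, fell, with log2 fold changes of -4.87 ± 0.27, -4.08 ± 0.26 and -3.38 ± 0.18, and nirB went from 1826 to 86.8 CPM in WT and from 1468 to 107 in recN. cusC, cusF and cusB, for copper export, fell likewise (-4.85 ± 0.22, -4.01 ± 0.27 and -3.36 ± 0.23). The nitrate reductase and transport genes napD, napF, narG and narK were at -3.58 ± 0.28, -2.98 ± 0.17, -3.13 ± 0.21 and -2.85 ± 0.19. The cell division list had 8 of 28 members lower and 0 higher, among them the genes minC, minD and minE that place the division site, at -2.08 ± 0.18, -1.87 ± 0.19 and -2.08 ± 0.18. In the purine and pyrimidine list 9 of 23 members rose and 0 fell, with purH at 1.52 ± 0.17 and purF at 1.36 ± 0.19. The colanic acid list had 7 of 22 higher and 0 lower, and the acid resistance list 5 of 14 lower and 0 higher, with gadE at -1.22 ± 0.28.

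In all, 491 genes rose and 561 fell at 20 min (edgeR, adjusted p under the threshold, 4298 genes tested). Camera with the preset correlation called the LexA list upwards (adjusted p = 1.01e-31), as it did the purine and pyrimidine (0.00141), colanic acid (0.0134), arginine, methionine and cysteine (0.0175), CP4 and CPS-53 prophage (0.0328) and e14 prophage (0.0456) lists. It called the cell division (6.85e-05), acid resistance (0.0175), histidine, tryptophan and branched-chain (0.0175) and ATP synthase and respiration (0.0448) lists downwards. With an estimated correlation none of the 26 lists passed: the LexA list had an adjusted p of 0.456 and the other 9 called lists an adjusted p of 0.8. Against random lists matched on expression, the LexA and the purine and pyrimidine lists were at the percentile 100 in both strains, colanic acid at 99 in WT and 99.1 in recN, e14 at 99.7 and 96.8, CP4 and CPS-53 at 99.9 and 90, and arginine, methionine and cysteine at 93.1 and 100. Of the downward calls, cell division was at 0.1 and 3.82, histidine, tryptophan and branched-chain at 0.17 and 9.18, acid resistance at 5.84 and 3.25, and ATP synthase at 29.6 and 17.1. With upper quartile scaling, which put the median of all genes at 0.16, 778 genes were higher and 388 lower, so that 66.7% of the calls were upwards against 46.7% with TMM, while DESeq2 called 175 up and 383 down and the fit without its covariate 153 and 314. The counts were 103 up and 187 down without untreated WT, 153 and 286 without WT at 40 min, 881 and 1023 without recN at 20 min, and 166 and 296 without recN at 40 min.

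The second comparison asked the same at 40 min. The LexA list had 29 of 33 members higher and 0 lower, with a median log2 fold change of 1.72, and 29 passed when adjusted over the list alone. Without recN itself the median was 1.53, against 1.49 at 20 min. In the direct comparison of 40 with 20 min the list's median without recN was -0.09, so the list as a whole did not rise further. Without WT at 40 min 18 members were higher. tisB rose by 4.86 ± 0.42 (edgeR adjusted p = 6.78e-05), dinI by 3.90 ± 0.30, sulA by 3.55 ± 0.33, recA by 3.45 ± 0.33, yebG by 3.28 ± 0.33, umuC by 3.22 ± 0.27 and umuD by 3.03 ± 0.19. The tRNA genes thrV and asnT rose by 3.30 ± 0.21 and 2.91 ± 0.28, where asnT has near-identical copies. Among all RNA classes, 66 of 86 tRNA genes and 22 of 22 rRNA genes rose at 40 min, while 938 of 4128 coding genes rose and 1039 fell. The rRNA genes held only 0.15% (untreated recN) to 0.74% (recN at 20 min) of the counts in a library. They include near-identical copies, so their number is not a number of separate results.

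Beyond the LexA list, members of several lists rose at 40 min, when 1044 of all 4298 genes rose and 1045 fell. In the list for ribonucleotide reductase and nucleotide pools 8 of 16 members rose and 1 fell: nrdA and nrdB, the aerobic ribonucleotide reductase, rose by 1.71 ± 0.22 and 1.31 ± 0.17, and ndk, nucleoside diphosphate kinase, by 1.41 ± 0.21. The e14 prophage had 10 of 17 members higher and 1 lower, with ymfJ at 1.52 ± 0.23 and croE at 1.48 ± 0.20. Of the CP4 and CPS-53 prophages 15 of 44 rose and 4 fell, of DLP12 12 of 23 rose and 2 fell, of Rac 4 of 23 rose and 0 fell, and of Qin 6 of 28 rose and 5 fell. In DLP12 the genes that fell, appY at -1.78 ± 0.26 and ompT at -1.48 ± 0.26, encode a regulator and an outer membrane protease. For colanic acid, an exopolysaccharide, 15 of 22 genes rose and 2 fell, with wza at 0.90 ± 0.18. In the arginine, methionine and cysteine list 8 of 30 rose and 3 fell, with argF at 1.82 ± 0.24 and metE at -1.11 ± 0.24. In the purine and pyrimidine list 9 of 23 rose and 3 fell, with pyrB at -1.47 ± 0.24.

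In most other lists more members fell than rose. The histidine, tryptophan and branched-chain list had 16 of 24 lower and 2 higher, with trpD, trpE and trpC at -2.80 ± 0.31, -2.68 ± 0.26 and -2.41 ± 0.27. The cell division list had 12 of 28 lower and 2 higher, with minE at -2.44 ± 0.19, and the ATP synthase and aerobic respiration list 13 of 28 lower and 1 higher, with cydA, of the oxidase for low oxygen, at -2.37 ± 0.24. For ribosomal proteins 18 of 54 fell and 0 rose, no more than in other highly expressed genes: the list stood at the percentiles 76.9 in WT and 62.7 in recN of random lists matched on expression. The acid resistance list had 10 of 14 lower and 1 higher (slp -1.97 ± 0.25), the OxyR list 11 of 16 lower and 0 higher (dps -1.10 ± 0.27), the RpoS list 11 of 26 lower and 1 higher (cbpA -1.67 ± 0.21) and the envelope stress list 11 of 19 lower and 2 higher (rpoE -1.33 ± 0.21, surA 1.49 ± 0.24). The flagella list had 18 of 51 lower and 1 higher (flgB -1.59 ± 0.19). Its median of -0.18 became 0.04 with upper quartile scaling, which put the median of all genes at 0.26. For the TCA cycle 8 of 16 fell and 2 rose (at 20 min its median was -0.04, its mean 0.18 and its test upwards), and for toxin-antitoxin genes 7 of 22 fell and 0 rose, but camera called neither list (adjusted p = 0.204 and 0.0938 with the preset correlation). The Fur list moved both ways, with 10 of 28 lower and 7 higher, and feoB, for ferrous iron uptake, at -2.41 ± 0.24. The lists for DNA repair outside LexA control (7 up and 6 down of 41, median -0.04 but test upwards, uvrC at -1.11 ± 0.18), SoxRS and MarA (1 up and 6 down of 20, soxS at 1.43 ± 0.36), heat shock (1 up and 3 down of 20, clpP at -0.99 ± 0.19) and the replisome (1 up and 2 down of 23, holD at 0.97 ± 0.18) were not called by camera. nirD, cusC, nirB and cusF again fell, at -4.48 ± 0.29, -4.50 ± 0.22, -3.90 ± 0.26 and -3.85 ± 0.27, as did fruK, for fructose use, at -3.27 ± 0.29.

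In all, 1044 genes rose and 1045 fell at 40 min (edgeR, 4298 genes tested). With the preset correlation camera called the LexA (adjusted p = 4.39e-20), e14 (0.00287), colanic acid (0.00324), ribonucleotide reductase (0.0212), CP4 and CPS-53 (0.037) and Rac (0.0398) lists upwards. It called the histidine, tryptophan and branched-chain list (0.000508), the cell division, acid resistance, ribosomal protein and ATP synthase lists (each 0.00303), OxyR (0.0153), RpoS (0.0212), flagella (0.0282) and envelope stress (0.0476) downwards. None passed with an estimated correlation, where the lowest adjusted p was 0.608, for the LexA list, and the other 14 called lists had an adjusted p between 0.624 and 0.67. Highly expressed genes were lower in general at 40 min, with medians of -0.45 in WT and -0.41 in recN in the most expressed of 4 equal groups. Against random lists matched on expression the histidine, tryptophan and branched-chain (percentiles 0.14 in WT and 0.02 in recN), flagella (0.13 and 0.08) and OxyR (0.93 and 0.04) lists were low in both strains. Envelope stress (8.63 and 0.25), acid resistance (10.5 and 2.61), RpoS (24.8 and 4.24), cell division (8.84 and 13.9) and ATP synthase (22.1 and 19.6) stood less low in one or both. Of the upward calls, LexA (100 in both), e14 (99.9 and 100) and colanic acid (100 and 98.4) stood highest over both strains, then CP4 and CPS-53 (98.1 and 96.8), ribonucleotide reductase (95.8 and 99.6) and Rac (95.4 and 92.2). With upper quartile scaling, which put the median of all genes at 0.26, 1487 genes were higher and 687 lower, so that 68.4% of the calls were upwards, while DESeq2 called 586 up and 886 down. The counts were 447 up and 537 down without untreated WT, 208 and 287 without WT at 40 min, and 214 and 303 without recN at 40 min.

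The third comparison set 40 min directly against 20 min. The 38 genes that rose held 24 tRNA genes, 5 small RNAs, 1 rRNA gene and 8 coding genes. Most are thus short RNAs, and whether such RNAs were favoured in library preparation stays open, as given in the section on flagged results. nrdA rose by 1.71 ± 0.22 (edgeR adjusted p = 0.0101) and nrdB by 1.37 ± 0.17, as did the LexA list member dinQ, an inner membrane peptide gene, by 1.37 ± 0.27. The 8 genes that fell included trpE at -1.32 ± 0.25 and rpoE, for the envelope stress sigma factor, at -1.10 ± 0.21. In edgeR 0 genes passed without WT at 40 min or without recN at 40 min. With all libraries 678 genes had an unadjusted p under 0.05, and DESeq2 called 62 up and 43 down. Camera with the preset correlation called the ribonucleotide reductase list higher (adjusted p = 6.4e-08) and the ribosomal protein (8.3e-09) and TCA cycle (3.6e-07) lists lower, but with an estimated correlation each had an adjusted p of 0.705. It also called the e14 list (0.00123) higher, and the histidine, tryptophan and branched-chain (0.000267), flagella (0.00218), ATP synthase (0.00331), purine and pyrimidine (0.00636), OxyR (0.00889), RpoS (0.0226) and envelope stress (0.0364) lists lower. With an estimated correlation these had an adjusted p of 0.705, and RpoS one of 0.844. The few residual degrees of freedom limit that setting here too. The counts of genes were 141 up and 343 down without WT at 20 min, 258 and 101 without recN at 20 min, 90 and 37 without untreated WT, and 93 and 37 without untreated recN.

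The fourth comparison asked what differs between recN and WT over the 3 conditions. Besides recN, which was lower by -9.66 ± 0.62, 17 genes were higher in recN and 0 lower (edgeR; 750 genes had an unadjusted p under 0.05). With recN counted among the lower genes, upper quartile scaling gave 9 higher and 1 lower, and the fit without its covariate 0 and 0. The highest were the e14 prophage genes ymfJ (b1144, 1201776 to 1202084), croE, ymfM and ymfL, at 2.23 ± 0.19 (adjusted p = 0.000423), 2.03 ± 0.16, 1.97 ± 0.17 and 1.63 ± 0.18, and rbsD, for ribose use, at 1.68 ± 0.19. ymfJ stood at 40.9, 47.6 and 86.1 CPM in WT and at 143, 221 and 542 CPM in recN. A difference between the strains in the sequence or copy number of e14 was not examined. The genes named as lower in all 3 conditions, asnU, asnV, ccmD, ugpA and ssuE, did not pass the test, with fitted values of -1.07, -1.06, -1.11, -0.88 and -0.79.

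As groups, camera with the preset correlation called the ribosomal protein (adjusted p = 5.34e-12), e14 (6.71e-11), arginine, methionine and cysteine (9.95e-08), ATP synthase (4.22e-07), envelope stress (0.000141), LexA (0.000247), heat shock (0.00484) and cell division (0.0309) lists higher in recN. None passed with an estimated correlation, where the adjusted p was between 0.716 and 0.789 over the 26 lists. Percentiles among random lists matched on expression are given for recN over WT untreated, at 20 and at 40 min. Heat shock had 74.4, 94.5 and 92.1, cell division 51.6, 98.3 and 86.5, and e14 100, 11 and 100. Envelope stress had 100, 96.8 and 97.3, and ATP synthase 97, 99.4 and 100. Ribosomal proteins had at least 99.2, but at 20 min their matched random lists already had a median of 0.40. The e14 call rests on few genes: 4 of 17 members passed, the list's median was 0.10 against a mean of 0.53, and its median log2 ratio of recN over WT was 0.33 untreated, -0.14 at 20 min and 0.48 at 40 min. The LexA list, in which recN itself was lower, had a median of 0.31 and a mean of 0.02, with 0 members higher past the threshold over all genes and 8 when adjusted over the list alone. Ribosomal proteins had a median of 0.39, with 1 of 54 higher. The counts of genes up and down, recN included, were 147 and 162 without WT at 20 min, 152 and 161 without recN at 20 min, 35 and 4 without untreated WT, 38 and 5 without untreated recN, 3 and 1 without WT at 40 min, and 4 and 1 without recN at 40 min. DESeq2 called 51 up and 15 down, and coding genes alone gave 56 and 10.

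Within each strain the values rest on 2 libraries and have no replicate check. sulA was at the top in WT at 20 min with a log2 ratio of 4.53, and tisB at 40 min with 5.83, while in recN sulA had 3.68 and 2.99. In WT 251 genes were at least 2-fold higher and 296 lower at 20 min, and 357 and 434 at 40 min. In recN the numbers were 133 and 141 at 20 min, and 221 and 324 at 40 min. Scaling by upper quartile shifted the median of all genes by 0.19 and 0.23 in WT and by 0.22 in recN at 40 min, and scaling by library totals by 0.27 and -0.41 in WT at 20 and 40 min. The balance in WT turned over under some of these, with more genes higher than lower. This held at 40 min with upper quartile and at 20 min with library totals. The LexA list had median log2 ratios of 1.37 and 1.59 in WT and 1.64 and 1.43 in recN at 20 and 40 min, each at the percentile 100 of matched random lists.

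**Figure D3:**
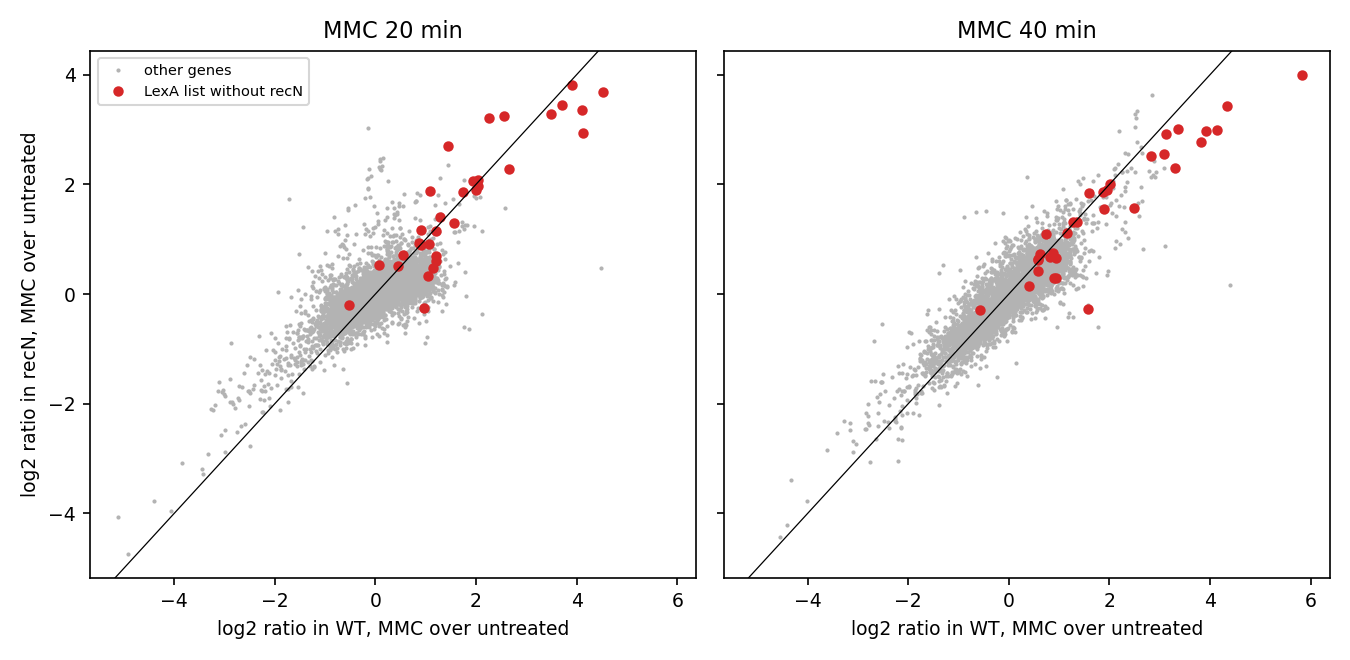
Log2 ratio of MMC over untreated in recN (vertical axis) against that in WT (horizontal axis) for each gene at 20 min (left) and 40 min (right), with LexA list members other than recN in red and the line of equal ratios. Pearson's r across genes was 0.722 at 20 min and 0.886 at 40 min.

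The responses of the strains were set against each other across genes, which are not independent replicates. Pearson's r was 0.722 at 20 min and 0.886 at 40 min, and Spearman's rho 0.684 and 0.872, with no library shared between the strains. Of 4298 genes, 77.9% had the same sign in both strains at 20 min and 87.5% at 40 min.

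Between the strains within a condition, LexA-controlled genes stood higher in untreated recN than in untreated WT. tisB was 4.34-fold higher (95% counting interval 3.51 to 5.40), yebG 2.93-fold (2.79 to 3.08), sulA 2.93-fold (2.72 to 3.15) and recA 1.79-fold (1.73 to 1.85), whereas uvrD was at 0.961-fold (0.893 to 1.03). The median log2 ratio of the list was 0.37 untreated, 0.42 at 20 min and 0.19 at 40 min, at the percentiles 100, 99.9 and 99.6. The LexA list was not alone in this. Untreated, the envelope stress (median 0.35) and ribosomal protein (0.34) lists also stood at the percentile 100. The arginine, methionine and cysteine list (0.18) stood at 99.8, and the lowest list was RpoS, at 2.98. Over all genes 29 were at least 2-fold higher and 43 lower in untreated recN, 92 and 23 at 20 min, and 35 and 62 at 40 min. This balance depends on scaling: with library totals the numbers were 40 and 138 at 20 min and 245 and 25 at 40 min. With coding genes alone 18 genes were lower at 40 min. That setting leaves out the tRNA, rRNA and small RNA genes and moved the scaling at 40 min by only 0.02. It also cut the lower counts untreated and at 20 min, as listed in the section on processing.

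The difference of response, recN minus WT, could not be tested. tisB had -1.20 at 20 min and -1.83 at 40 min, sulA -0.84 and -1.15, and yebG -0.76 and -1.06. In untreated recN these genes stood 4.34-, 2.93- and 2.93-fold higher than in untreated WT. That ratio is subtracted here, so a higher untreated level alone lowers the value. The LexA list's median ratio of recN over WT stayed above 0 after MMC, at 0.42 and 0.19. Negative values here therefore do not mean lower levels in recN. Over the LexA list the median was -0.05 at 20 min and -0.22 at 40 min, at the percentiles 2.45 and 0.19, but with library totals, which shifted all genes by -0.26 and 0.49, these medians were -0.31 and 0.28. The genes named with a higher response in recN were mgrR (3.45 and 0.73), rrlA (3.18 and 0.08), ccmA (1.28 and 2.30), frdD (1.36 and 1.82) and fnrS (1.98 and 0.96). Those with a lower response were ynbG (-1.29 and -2.37), ileY (-2.50 and -1.17), yoaG (-2.35 and -1.10), ibsB (-1.89 and -1.56) and ymgC (-1.81 and -1.56). Of the genes named with a higher response, rrlA is an rRNA gene. Over the 22 rRNA genes the median difference was 2.16 at 20 min and 0.17 at 40 min. The rRNA share of the counts was highest in recN at 20 min, at 0.74%. The value of rrlA therefore does not stand for that gene alone.

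**Figure D4:**
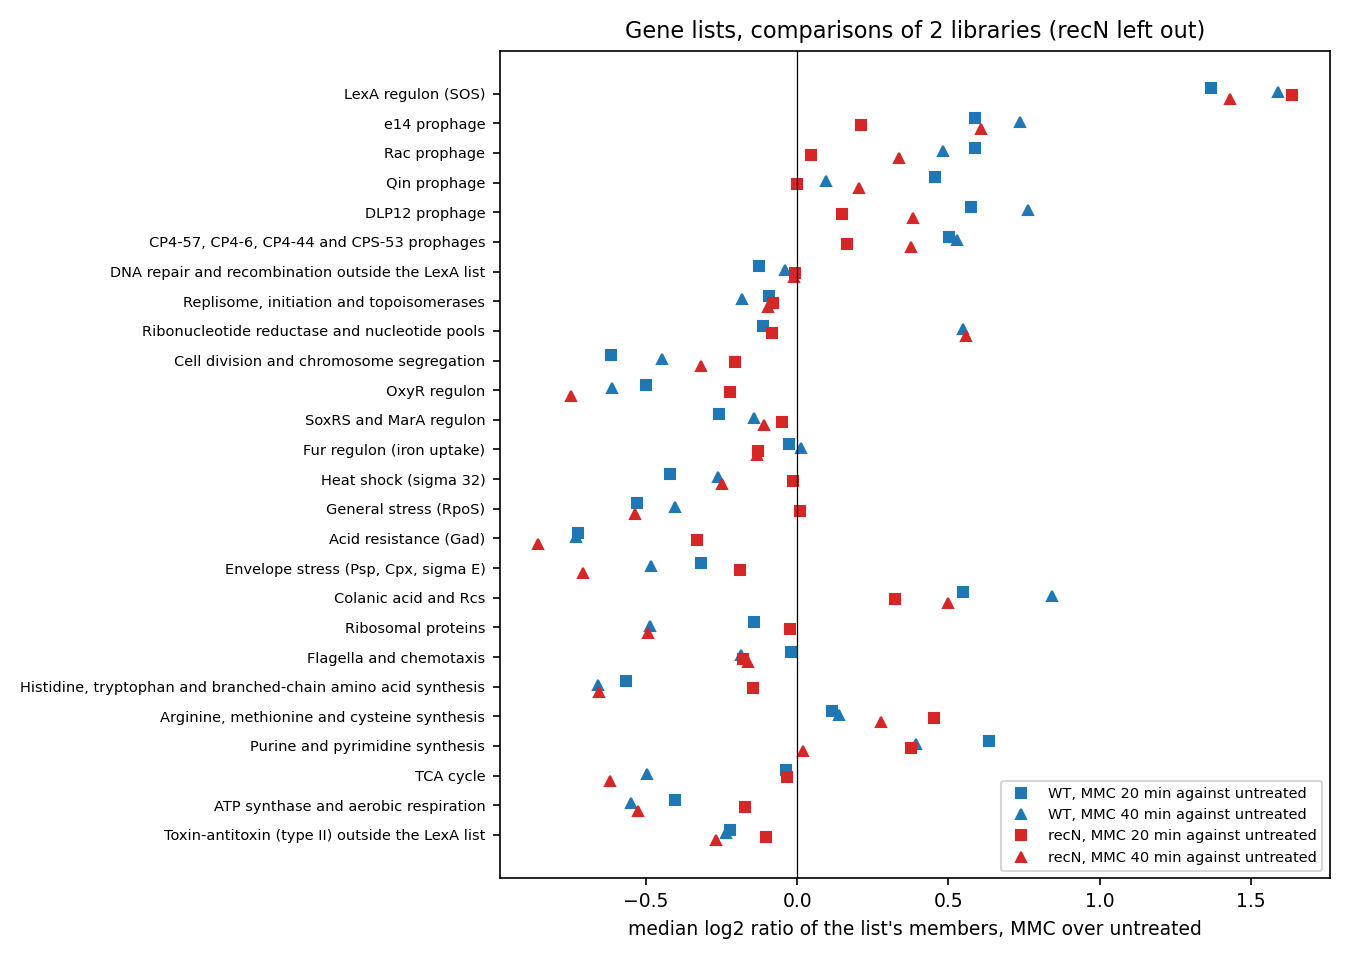
Median log2 ratio of each gene list's members (horizontal axis) for the 26 lists (vertical axis) in the 4 comparisons of 1 MMC library with 1 untreated library. The LexA list lies at 1.37 and 1.59 in WT and at 1.64 and 1.43 in recN.

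The log2 ratio was set against distance from oriC, the origin of replication, taken at 3925822, because MMC cross-links block replication. At 40 min the ratio was lower farther from the origin: the slope was -0.20 per Mb in WT (95% interval over genes -0.24 to -0.16) and -0.19 in recN (-0.22 to -0.15). With genes in 4 equal groups by distance, the medians from nearest to farthest were 0.12, 0.21, -0.04 and -0.19 in WT and 0.13, 0.14, 0.01 and -0.16 in recN, so that the nearest group was not the highest. At 20 min the slopes were -0.05 in WT (-0.08 to -0.01) and -0.10 in recN (-0.12 to -0.07). For recN against WT the slope was 0.04 (0.02 to 0.06) untreated, -0.01 (-0.03 to 0.01) at 20 min and 0.05 (0.03 to 0.07) at 40 min. Libraries without MMC thus differed by a slope close in size to that of WT at 20 min. Intervals over genes do not cover the spread between libraries, so the WT slope at 20 min cannot be ascribed to MMC.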

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

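The tests of RNA length and of recN carry-over, and the admixed shares over 59 and over 88 genes, were chosen only after the result was seen.

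Of the 10 genes named for the difference of response, the only genes looked at in this way, 3 had both MMC libraries of one strain moved opposite to both of the other. The difference was not tested. Both ratios of a strain share its 1 untreated library, so a deviant untreated value alone could give this pattern. The genes had also been picked for a large difference at both times. ileY, a tRNA gene, had log2 ratios of 1.86 and 1.02 in WT and -0.64 and -0.15 in recN at 20 and 40 min. ibsB, a small toxin gene, had 0.99 and 0.96 in WT and -0.90 and -0.61 in recN. ymgC had 1.03 and 1.21 in WT and -0.78 and -0.35 in recN.

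The predicted RNAs, which no comparison used, held more of the counts in WT at 20 min (3.53%), WT at 40 min (2.97%) and recN at 40 min (3.33%) than in untreated WT (2.11%). In recN they held 1.38% untreated and 2.06% at 20 min.

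Stable RNAs took more of the counts at 40 min in both strains. A distortion of the scaling of coding genes by these RNAs is argued against: with coding genes alone, 99.6% of the coding genes called at 40 min were kept with the same sign. Whether short RNAs were favoured in library preparation stays open, since the change fell with RNA length over 56 small RNAs with a Spearman's rho of -0.34 in WT and -0.18 in recN, and the interval in recN was -0.42 to 0.11. A biological change of stable RNA relative to mRNA after MMC was not tested and may also account for the pattern.

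LexA-controlled genes stood higher in untreated recN than in untreated WT. Carry-over from treated WT is argued against, since recN in untreated recN was at 0.0422% of its level in WT at 20 min while the LexA genes would need a median of 8.69%, and so is scaling, since the lowest median log2 ratio over the scalings was 0.33. For carry-over from treated recN, 99 genes outside the list had a median admixed share of -10.8% (interval -15.3 to -2.66), below the lower quartile of 3.61% of the LexA genes, but they were picked by their rise over untreated recN, which itself lowers the share. Picked by their rise over the mean of both untreated libraries, 88 genes had 5.63% (0.0128 to 10.9; LexA lower quartile 3.83%), and the 59 of the 99 genes at least 2-fold above untreated WT had 3.83% (-0.813 to 8.36), so that this explanation cannot be told apart from a raised SOS level. A raised SOS level in cells without RecN is a hypothesis that rests on 1 library per strain. The envelope stress and ribosomal protein lists stood at the same percentile as the LexA list in this comparison.

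As 1 joined list, prophage genes outside the LexA list were higher after MMC. This did not hold for each prophage: Qin had 0 of 28 genes up and 3 down at 20 min and 6 up and 5 down at 40 min, and stood at the percentiles 99 and 44.6 in WT and 36.3 and 74.9 in recN. A general rise of weakly expressed genes could account for part of this, since the least expressed of 4 equal groups of genes had medians of 0.32 and 0.42 in WT and 0.15 and 0.34 in recN at 20 and 40 min. Against matched random lists the 135 prophage genes stood at the percentile 100 in WT at both times and in recN at 40 min, but at 92.8 in recN at 20 min, so that in that library the explanation stays open.

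For recN against WT, 18 genes passed, recN itself among them, and the highest of the other splits gave 0. Every other split leaves the strain difference, the loss of recN included, in its spread. Most of them also do not set the 2 libraries of each condition apart. The contrast was therefore largely fixed in advance, and no conclusion is drawn from it. Of the 10 splits of the 6 libraries, 1, the real one, gave as many, and 10 splits are too few for a share under 0.05.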

How the results depend on the processing

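The scaling from coding genes was chosen only after the result was seen. Over 309 results for named genes, 3896 alternatives kept direction and side of the threshold, 336 lost the call, 74 gained it and 0 turned. For list medians of the additive fit these numbers were 1131, 82, 34 and 1, and for medians of 2 libraries 2137 kept, 178 moved and 25 turned. The cause was not tested, except that fewer genes were tested with coding genes alone and fewer libraries entered each fit without a library. With 1 library left out, the lone library of its condition is assumed to vary like the others. Depth limits genes with few counts, of which up to 55 per library had under 10.

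With DESeq2, values were MMC 20 min, higher 175, MMC 40 min, higher 586, MMC 40 min against MMC 20 min, higher 62, MMC 40 min against MMC 20 min, lower 43, recN against WT, higher 51 and recN against WT, lower 15. With upper quartile, values were MMC 20 min, higher 778, MMC 40 min, lower 687, MMC 40 min against MMC 20 min, lower 3, recN against WT, higher 9, median of Flagella and chemotaxis, MMC 40 min 0.0435 and WT, MMC 20 min, genes 2-fold higher 477. With upper quartile, values also were WT, MMC 40 min, genes 2-fold higher 734, WT, MMC 40 min, genes 2-fold lower 271, recN, MMC 40 min, genes 2-fold higher 440, recN, MMC 40 min, genes 2-fold lower 204, MMC 20 min, recN against WT, genes 2-fold lower 48 and difference at 20 min, genes 2-fold lower 132. With upper quartile, values also were median of replisome, WT, MMC 20 min 0.0991, median of Ribosomal proteins, WT, MMC 20 min 0.051, median of replisome, WT, MMC 40 min 0.0421, median of Flagella and chemotaxis, WT, MMC 40 min 0.0403, median of Flagella and chemotaxis, recN, MMC 40 min 0.057 and median of replisome, difference at 20 min -0.0443. With no covariate, values were MMC 20 min, higher 153, MMC 20 min, lower 314, MMC 40 min against MMC 20 min, higher 14, MMC 40 min against MMC 20 min, lower 1, recN against WT, higher 0 and recN against WT, lower 0. With coding genes alone, values were MMC 40 min against MMC 20 min, higher 17, MMC 40 min against MMC 20 min, lower 18, recN against WT, higher 56, recN against WT, lower 10, recN, MMC 20 min, genes 2-fold higher 73 and untreated, recN against WT, genes 2-fold lower 12. With coding genes alone, values also were MMC 20 min, recN against WT, genes 2-fold lower 12, MMC 40 min, recN against WT, genes 2-fold lower 18 and difference at 40 min, genes 2-fold lower 27. With size factors of DESeq2 in edgeR, values were recN against WT, lower 2. With no filter, values were recN against WT, lower 2. With scaling from coding genes, values were recN against WT, lower 2. With library totals, values were WT, MMC 20 min, genes 2-fold higher 618, WT, MMC 20 min, genes 2-fold lower 189, WT, MMC 40 min, genes 2-fold higher 127, WT, MMC 40 min, genes 2-fold lower 1013, MMC 20 min, recN against WT, genes 2-fold higher 40 and MMC 20 min, recN against WT, genes 2-fold lower 138. With library totals, values also were MMC 40 min, recN against WT, genes 2-fold higher 245, MMC 40 min, recN against WT, genes 2-fold lower 25, difference at 20 min, genes 2-fold higher 87, difference at 20 min, genes 2-fold lower 242, difference at 40 min, genes 2-fold higher 333 and difference at 40 min, genes 2-fold lower 13. With library totals, values also were median of replisome, WT, MMC 20 min 0.18, median of Ribosomal proteins, WT, MMC 20 min 0.13, median of toxin-antitoxin, WT, MMC 20 min 0.0494, median of replisome, MMC 20 min, recN against WT -0.18, median of cell division, MMC 20 min, recN against WT -0.0203 and median of OxyR regulon, MMC 20 min, recN against WT -0.0546. With library totals, values also were median of SoxRS and MarA regulon, MMC 20 min, recN against WT -0.0843, median of TCA cycle, MMC 20 min, recN against WT -0.14, median of Colanic acid and Rcs, MMC 40 min, recN against WT 0.32, median of LexA regulon (SOS), difference at 20 min -0.31, median of replisome, difference at 20 min -0.20 and median of cell division, difference at 20 min -0.0116. With library totals, values also were median of SoxRS and MarA regulon, difference at 20 min -0.0496, median of Ribosomal proteins, difference at 20 min -0.0783, median of LexA regulon (SOS), difference at 40 min 0.28, median of Rac prophage, difference at 40 min 0.31, median of DLP12 prophage, difference at 40 min 0.30 and median of Colanic acid and Rcs, difference at 40 min 0.22. With library totals, values also were median of Purine and pyrimidine synthesis, difference at 40 min 0.29 and median of TCA cycle, difference at 40 min 0.37. With prior count 8, values were untreated, recN against WT, genes 2-fold higher 18 and MMC 20 min, recN against WT, genes 2-fold lower 14. With filter of 50 counts, values were difference at 40 min, genes 2-fold lower 29 and correlation of responses, 40 min 0.898.

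Leaving out each library in turn gave ranges of MMC 20 min, higher 103 to 881, MMC 20 min, lower 187 to 1023, MMC 40 min, higher 208 to 1348, MMC 40 min, lower 287 to 1340, MMC 40 min against MMC 20 min, higher 0 to 258. Ranges also were MMC 40 min against MMC 20 min, lower 0 to 343, recN against WT, higher 3 to 152, recN against WT, lower 1 to 162, LexA list members higher, MMC 40 min 18 to 29.

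The model already pairs libraries by strain, and the fit without this covariate is given above. Beyond this no paired analysis was possible by replicate number, because each group holds 1 library.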

Other observations

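The tests of these 3 lists, and the genes named from them, were chosen only after the result was seen. Many genes for anaerobic respiration and most for copper export and uptake of fructose and galactitol fell, in lists written after the values were seen and therefore not independent of them. In the anaerobic respiration list 35 of 64 genes fell and 3 rose at 20 min, and 34 fell and 5 rose at 40 min. dmsA, of dimethyl sulfoxide reductase, was at -2.74 ± 0.21, frdA, of fumarate reductase, at -2.39 ± 0.34 and nrfA, of nitrite reductase, at -1.62 ± 0.17 at 20 min, whereas hyaE, of the hydrogenase operon hya, rose by 1.27 ± 0.42 at 40 min. In the copper list 8 of 9 genes fell at each time, with the exporter copA at -1.42 ± 0.20 at 40 min. In the fructose and galactitol list 8 of 8 fell at each time, with gatA at -2.90 ± 0.26 and fruA at -2.53 ± 0.25 at 40 min.

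Among the predicted RNAs of the deposited tables, 63 overlapped on the same strand in all 4 MMC libraries and in neither untreated library, and 37 of these were antisense to a gene. The MMC libraries held more predicted RNAs: 738 and 623 in WT and 397 and 717 in recN, against 363 and 226 untreated. The reverse count was not made, so the 63 have no baseline. In WT at 20 min 447 of the 738 were antisense, a share like that among the 63. One lay antisense to sulA (1020817 to 1020879), with 251 and 193 counts in WT and 322 and 198 in recN at 20 and 40 min. Since it is not stated whether counting used strand, such reads cannot be told apart from those of sulA itself.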
